A study of Mus musculus with 15 samples.

How the data were processed

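RNA was measured in day 12 organoids grown from SpretB6 mouse lines, which carry a genome copy from C57BL/6J (B6) and a genome copy from Mus spretus (Spret), so that each library holds transcripts of both alleles of a gene. There were 3 organoid libraries, and the table held 1 B6 column and 1 Spret column for each. The growth protocol in the labels describes organoids derived from epiblast stem cells, while the tissue label names the stem cells themselves. The table is named as day 12 organoids and was treated as such. The series also lists 12 induced pluripotent stem cell samples from 4 crosses, 3 per cross, which were not analysed here. Nothing in the labels says whether the 3 libraries, titled as clones C1 to C3, came from separate cultures on separate days, so the p-values measure the spread between these 3 libraries, which may be technical in part.

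The values are a score: per the name of the deposited table they are allele-specific normalised read numbers per gene, rounded to whole numbers. The libraries were made after ribosomal RNA depletion with 80M reads planned per sample, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the way reads were assigned to an allele, the counting tool and its use of strand are not given for these libraries in the sources used here. The values themselves carry the trace of a scale: up to a value of 200, 27 whole numbers in library 1 and 43 in library 2 held 0 genes in either allele column, as happens when whole reads are multiplied by a factor above 1 and rounded. In library 3 no number was empty, but numbers alternated in how many genes they held, as happens when a factor below 1 rounds a pair of neighbouring read numbers to the same value. The factors that fitted these patterns best by likelihood were 1.156 for library 1, 1.276 for library 2 and 0.672 for library 3. Between 20 and 180, the 78 numbers that this last factor reaches from 2 read numbers held 1.92 times as many genes, relative to the numbers around them, as the 83 that it reaches from 1. Each was estimated on both allele columns of a library together. A factor below 1 merges neighbouring read numbers, so reads could not be recovered exactly in library 3, and tests for read counts were not used.

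Depth limits the values. The B6 columns summed to 2701847, 2413876 and 3027078 in libraries 1, 2 and 3, and the Spret columns to 2337998, 2088788 and 2639912. Divided by the estimated factors these are about 2.34M, 1.89M and 4.51M B6 reads and 2.02M, 1.64M and 3.93M Spret reads, so library 3 had the most reads behind its values. Only reads that could be assigned to an allele enter the table. No pair of columns was identical, and pairs of libraries differed by more than counting noise in both alleles, with a chi-square per degree of freedom from 2.75 to 6.01. All 6 allele columns were used, and the table held 44260 genes.

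Gene names were matched to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. A position was found for 42531 genes there and for 979 more in the RefSeq annotation of the same assembly, which leaves 750 without a position. Ratios were taken as log2(Spret value + 1) minus log2(B6 value + 1), which understates the differences of low genes. Genes with a mean value of at least 10 over the 6 allele columns were tested, 15985 in all. The test was limma 3.58.1 in R 4.3.3 with library and allele as terms and an intensity trend, which is the paired difference of the alleles within a library. The pairing comes from the material, since both alleles were read from the same RNA. P-values were two-sided and adjusted by the Benjamini-Hochberg method over tested genes, with a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 12.3. A test for read counts had been set aside for the case of a table of raw reads, which did not apply.

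Gene lists were fixed before the data were examined, 23 in all, for forebrain cell types, other tissues, imprinting, the mitochondrial genome, ribosomal proteins, metabolism, cell cycle and signalling. The mitochondrial list had no gene in the table, and the endoderm and epidermis list had 2 tested genes. The other 21 lists, with at least 5 tested genes each, were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation, with fry and with Fisher's exact test of called genes in each direction. The genes named were also chosen by a rule written before the data were examined. Its first part takes the 8 genes with the largest ratios in each direction among called genes whose ratio had the same sign in all 3 libraries and whose summed value was at least 100. Genes whose weaker allele had a mean under 5 were kept apart as a group, with the 4 of highest summed value named. Its other parts take the called member of highest summed value per list and direction, up to 10 called imprinted genes, and the 3 members of highest summed value in each cell type list. Genes outside the rule were chosen after their values were seen, among them Clcn4, Gm45631, Zfp418, Gm24187, Snrpn, Peg3, Nnat, the Y-linked genes and those of the Meg3 domain. Some genes that the rule takes are not reported here.

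The test was tried on simulated data made from the same genes and libraries, with 15289 genes. Of 50 genes changed by each size, 30% of 1.5-fold, 68% of 2-fold, 96% of 4-fold and 100% of 8-fold changes were called with the right sign, and among the 1.5-fold changes these were 1 of 21 genes with a mean value below 50 and 14 of 29 others. In the same data 0.0133% of 15050 unchanged genes were called. Alleles were simulated independently with a preset spread, without any general lean to an allele, and few genes were changed. These shares therefore do not give the error rate or the power of the test on the deposited values. Alternatives covered the pseudocount (0.5 and 5), the filter on low values (none, a mean of 50, both alleles at 5), the paired term, each library left out in turn, ratios centred on a median of 0, limma without the trend, and the genes left after X-linked and imprinted genes were taken out. Shares for a single library carry Wilson 95% intervals from the estimated reads, which cover counting error only. Tables and plots were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.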

Results

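Allele-specific expression was measured in organoids that model the cerebral cortex, grown from hybrid mouse lines whose cells hold a B6 and a Spret copy of each autosome. Both copies sit in the same nuclei, so the alleles are compared within the same cells. The design asks which genes differ in this way between mice separated by evolution. There were 3 libraries of day 12 organoids, each with a B6 value and a Spret value per gene. Values are normalised read numbers as the authors deposited them, with sums of 2701847, 2413876 and 3027078 for B6 and 2337998, 2088788 and 2639912 for Spret in libraries 1, 2 and 3.

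The organoids expressed genes of the dorsal forebrain, its intermediate progenitors and its excitatory neurons at high levels. Summed over both alleles, the neuronal genes Map2, a microtubule protein of dendrites, Dcx, a microtubule protein of migrating neurons, and Neurod6, a transcription factor of cortical excitatory neurons, stood at 8885 ± 934, 5906 ± 516 and 4259 ± 940 normalised values (mean ± SD, n = 3). The progenitor genes Ptprz1 and Cdh2 stood at 2367 ± 439 and 2197 ± 131, and the intermediate progenitor genes Eomes, Rnd2 and Chd7 at 1374 ± 248, 1053 ± 51.6 and 985 ± 215. Reln, the secreted protein of Cajal-Retzius cells, reached 1102 ± 356, with Nr2f2 at 398 ± 172 and Cacna2d2 at 175 ± 53.1. Gad1 and Zic4 of the ventral telencephalon list stood at 113 ± 22.6 and 107 ± 61.5. Lhx9, Tcf7l2 and Barhl2 of the eye and posterior neural list stood at 312 ± 87.0, 67.0 ± 23.5 and 48.7 ± 17.2. Zic2, Otx2 and Klf4 of the pluripotency list stood at 164 ± 40.2, 83.3 ± 52.6 and 82.0 ± 11.4, and Dcn, Tfap2b and Pdgfra of the mesenchyme and neural crest list at 175 ± 22.5, 104 ± 41.6 and 77.3 ± 18.1. Of the endoderm and epidermis list, Ttr, shared with the choroid plexus list, and Trp63 were the 2 of 20 genes abundant enough to test. Ttr stood at 1137 ± 1232, Trp63 at 24.0 ± 14.1 and the untested Gata6 at 16.3 ± 13.8.

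Genes of the cortical hem and choroid plexus list were among those whose level differed between libraries. Ttr, the transport protein made by choroid plexus and also a member of the endoderm list, summed to 2555 in library 1, 534 in library 2 and 323 in library 3, a mean of 1137 ± 1232 (SD, n = 3). Rspo3, a Wnt agonist of the hem, went from 398 to 212 and 149 across the same libraries, with a mean of 253 ± 129, and Foxj1, a regulator of motile cilia, had a mean of 151 ± 115. Some genes of other lists were also highest in library 1, with Reln at 1509, 851 and 945, Lhx9 at 412, 270 and 254, Zic4 at 178, 70 and 73, Otx2 at 144, 56 and 50, and Tfap2b at 152, 81 and 79 in libraries 1, 2 and 3. Others were not. Nr2f2 and Cacna2d2, in the Cajal-Retzius list with Reln, were highest in library 3, at 344, 259 and 591 and at 178, 120 and 226. These differences between single libraries were not tested.

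**Figure D1:**
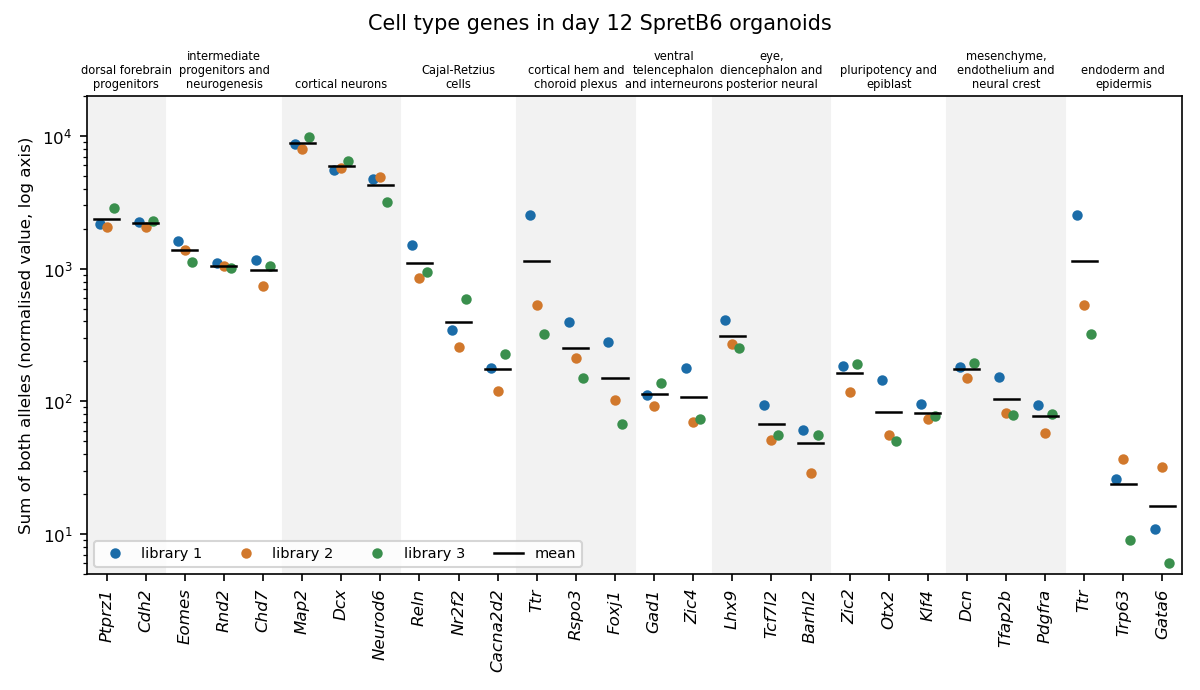
Summed value of both alleles (normalised read number, log axis) for abundant genes of each cell type list, with a point per library and a bar at the mean of 3 libraries. Map2 has the highest mean, 8885, while Ttr, shown under both lists that hold it, ranges from 323 to 2555.

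The sex chromosomes were read from opposite alleles. Over X-linked genes the Spret columns held 0.0941% ± 0.00595 of all values (SD, n = 3), and all 438 tested X-linked genes were higher from B6. Of these, 349 had a Spret value of 0 in every library. Over Y-linked genes the Spret columns held 99.5% ± 0.280, and all 5 tested genes, Eif2s3y, Ddx3y, Uty, Uba1y and Kdm5d, were higher from Spret. Ddx3y, an RNA helicase, read 234 ± 16.6 from Spret and was listed at 0 from B6. These values point to cells with an X from B6 and a Y from Spret. X-linked and Y-linked genes then have no other allele to compare, and their calls are not differences between alleles. In such cells B6 is the maternal and Spret the paternal copy of each autosome. No library of the reverse cross was analysed, so strain and parental origin cannot be told apart in any autosomal call. Autosomal values came from Spret at 47.7% ± 0.137, slightly below equal shares. The median log2 ratio of Spret to B6 was -0.13 over 15452 autosomal genes, and it was below 0 in all 57 combinations of autosome and library. Chromosome means of that median ranged from -0.16 to -0.07.

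**Figure D2:**
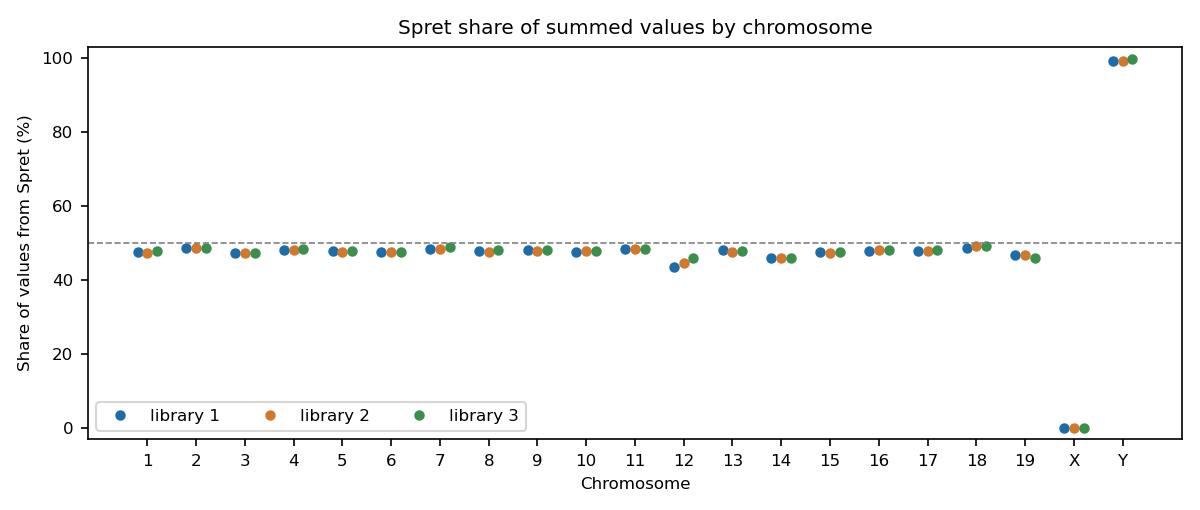
Share of all values that came from Spret (%, vertical axis) for each chromosome, with a point per library and a dashed line at equal shares. Autosomes lie just under the line, chromosome X near 0 with a mean of 0.0941% and chromosome Y near the top with a mean of 99.5%.

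Allelic differences were common on autosomes. Among 15985 tested genes, 4852 differed between alleles by limma, 1209 higher from Spret (24.9%) and 3643 higher from B6. When each library's ratios were centred, which removed shifts of -0.14, -0.14 and -0.13, 4616 genes were called, 2214 of them (48.0%) higher from Spret. On autosomes alone 4159 were then called, 2205 higher from Spret and 1954 from B6. The balance of directions therefore depends on this scaling, and on autosomes the larger side changes with it. Without centring, 4393 autosomal genes were called, 1202 higher from Spret and 3191 from B6. Their median difference was 1.56-fold, with quartiles of 1.33 and 2.03, and 1134 of them differed at least 2-fold, 289 toward Spret and 845 toward B6. Over all tested genes, 1586 differed at least 2-fold. The counts of 4852 and 1586 include 438 X-linked and 5 Y-linked genes, which were read from a single copy. How reads were assigned to an allele is not given in the sources used here, and a method that favours the B6 reference would add to the calls toward B6. Ratios of autosomal genes correlated between libraries at r = 0.609, 0.654 and 0.603, across genes, which are not independent replicates. The number of called genes fell to 2667 without library 1, to 1537 without the paired term, to 2229 without limma's trend and to 1236 with no filter on low values. The number with a 2-fold difference fell to 854 with no filter, to 592 at a mean value of at least 50 and to 985 where both alleles had a mean of at least 5.

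Among genes whose weaker allele had a mean value of at least 5, those that leaned most to Spret were led by Acot1, a cytosolic acyl-CoA thioesterase on chromosome 12 (84009490 to 84018371, mm10). Acot1 read 122 ± 14.7 from Spret and 14.3 ± 1.53 from B6 (SD, n = 3), a log2 ratio of 3.00 ± 0.21 (SE, limma adjusted p = 2.52e-08). Next came Tuba1c, an alpha tubulin, at 2.64, the small nucleolar RNA Gm24336 at 2.54, Klhl22, a substrate adaptor of a cullin ubiquitin ligase, at 2.53, Podn, a matrix proteoglycan, the transcript 1700007J10Rik at 2.49, Pcnx2 at 2.25 and the ribosomal protein gene Rpl36al at 2.25. Adjusted p-values of these 8 genes were at most 5.1e-06. The ratio was above 0 in 3 of 3 libraries for each. With no filter on low values the calls of Tuba1c, Klhl22 and Podn ended (adjusted p = 0.0573, 0.0757 and 0.0625).

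Toward B6, with the same limit on the weaker allele, the list opened with the X-linked Tmsb4x, an actin-binding peptide, which read 2255 ± 330 from B6 and 10.3 ± 2.52 from Spret, a log2 ratio of -7.65. On autosomes Sphkap, an anchoring protein of protein kinase A, on chromosome 1 (83254139 to 83408200) read 580 ± 4.93 from B6 and 47.7 ± 11.7 from Spret, a log2 ratio of -3.60 ± 0.12 (SE, limma adjusted p = 8.05e-12). The long noncoding RNA 2600014E21Rik had a ratio of -4.04. The histone genes H2ac15 and H3c3 on chromosome 13 had ratios of -4.54 and -4.23, and the annotated microRNA genes Gm44454 and Gm26377 had -4.87 and -2.71. Each of these genes was lower from Spret in 3 of 3 libraries, with adjusted p-values of at most 1.15e-07. Values of Acot1, Tuba1c, Rpl36al and the histone genes are uncertain, since each belongs to a family of close copies whose reads could be split, and those of the short RNAs because the treatment of overlapping genes is not given. In libraries 1, 2 and 3, H2ac15 read 695, 468 and 414 from B6, and Gm44454 read 674, 457 and 398. Both lie on chromosome 13, and whether they count the same reads was not tested.

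In 271 called genes with a summed value of at least 100 and the same sign in all libraries, the weaker allele had a mean value under 5. Of these, 251 lie on chromosome X and were read from B6, 4 lie on chromosome Y, 8 autosomal genes were read from B6, 7 autosomal genes were read from Spret and 1 gene had no position. The 4 of highest summed value were the small nuclear RNA Gm22513 on chromosome 12 (14753 ± 9242 from B6 and 0.333 ± 0.577 from Spret), the X-linked Dcx (5903 ± 516 and 2.67 ± 2.08), Ccnb1ip1 on chromosome 14 (5305 ± 1396 and 1.33 ± 1.53) and the X-linked chromatin remodeller Atrx (4762 ± 635 and 1.00 ± 0). Further autosomal members were named after their values were seen. Clcn4, a chloride and proton exchanger on chromosome 7, read 821 ± 43.6 from B6 and was listed at 0 from Spret. Gm24187 on chromosome 13 read 158 ± 37.7 from Spret and was listed at 0 from B6.

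Genes of the dorsal forebrain lineage went both ways, mostly by small amounts. Of 26 tested progenitor genes, 5 were higher from Spret and 4 from B6, with 10 called when adjusted over the list alone. Fabp7, the fatty acid binding protein of radial glia, was higher from Spret (log2 ratio 0.25 ± 0.06) and the nuclear receptor Nr2f1 higher from B6 (-0.34 ± 0.07). Of 20 genes of intermediate progenitors, 4 were higher from Spret, among them Chd7 (0.26 ± 0.07), and 7 from B6, among them Eomes (-0.27 ± 0.06) and Rnd2 (-0.35 ± 0.08), with 11 called when adjusted over the list alone. Of 30 cortical neuron genes, 3 were higher from Spret, among them Map2 (0.10 ± 0.03), and 12 from B6, among them the X-linked Dcx and Neurod6 (-0.13 ± 0.04), with 17 adjusted over the list alone. The progenitor list also holds 1 X-linked gene, called toward B6 as all tested X-linked genes were. Ptprz1 and Cdh2 were not called, with ratios of 0.11 and -0.01. With centred ratios the counts for Spret and B6 were 8 and 3 in progenitors, 5 and 4 in intermediate progenitors and 5 and 8 in neurons. Eomes and Rnd2 then lost their calls (adjusted p = 0.137 and 0.0559), Neurod6 moved to 0.01, and Ptprz1 gained a call (adjusted p = 0.00142). Leaving out library 1 ended the calls of Nr2f1, Chd7, Eomes, Map2, Rnd2 and Neurod6 (adjusted p from 0.0504 to 0.103). Without library 2 those of Fabp7, Chd7, Map2, Rnd2 and Neurod6 ended (0.0544 to 0.18), and without library 3 those of Fabp7, Map2 and Neurod6 (0.0576 to 0.204). The calls of Fabp7, Nr2f1, Chd7, Eomes, Rnd2, Map2 and Neurod6 also ended without limma's trend (0.139 to 0.562), with no filter on low values (0.12 to 0.201) and without the paired term (0.208 to 0.806), and that of Map2 with a pseudocount of 0.5 (0.0611).

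Among 12 Cajal-Retzius genes, 1 was higher from Spret, the transcription factor Lhx5 (0.78 ± 0.27), and 5 were higher from B6, among them Nr2f2 (-0.88 ± 0.11) and Reln (-0.18 ± 0.06), with 6 adjusted over the list alone. Of 17 genes of the cortical hem and choroid plexus, 5 were called, all higher from B6, with 5 adjusted over the list alone. Ttr led them at -1.68 ± 0.09, with 880 ± 964 from B6 and 257 ± 268 from Spret. Its ratio held in 3 of 3 libraries although the level of Ttr differed between them. Rspo3 had a ratio of -0.41 ± 0.13. Calls in the other cell type lists can be set against the 30.4% called over all tested genes. They were 1 of 6 ventral genes, 2 of 10 eye and posterior genes with Lhx9 (-0.55 ± 0.14), 4 of 12 pluripotency genes with the reprogramming factor Klf4 (-1.34 ± 0.30), and 2 of 13 mesenchyme genes, Dcn (0.63 ± 0.16) and Prrx1 (-1.35 ± 0.27). Adjusted over the list alone these 4 counts were 1, 2, 5 and 2, and 1 of the pluripotency genes is X-linked. With centred ratios the counts for Spret and B6 were 1 and 3 in Cajal-Retzius genes and 0 and 3 in hem and choroid plexus genes. Those of the other 4 lists stayed as they were. Reln and Rspo3 lost their calls with centred ratios (limma adjusted p = 0.653 and 0.155). Without library 1, Lhx5, Reln, Lhx9, Klf4, Dcn and Rspo3 lost theirs (0.0929 to 0.324), with Lhx9 at a ratio of -0.35. Without library 2, Lhx5 and Reln did (0.221 and 0.0791), with Lhx5 at 0.45, and without library 3, Lhx5, Reln, Dcn and Rspo3 (0.0645 to 0.138). The calls of Lhx5, Reln, Lhx9, Dcn and Rspo3 also ended without limma's trend, with no filter and without the paired term (0.0911 to 0.742), and that of Lhx5 with a pseudocount of 0.5 (0.0509). Klf4 lost its call without the trend and with no filter (0.0983 and 0.22), Nr2f2 with no filter and without the paired term (0.0691 and 0.161), Prrx1 with no filter (0.0921) and Ttr without the paired term (0.217).

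Ribosomal protein genes were the only list of 21 that camera placed apart from the other genes. Of 80 tested members, 30 were higher from Spret and 18 from B6, with 50 called when adjusted over the list alone, 31 and 19. Rpl23 read 1895 ± 237 from Spret and 1113 ± 187 from B6 (log2 ratio 0.77 ± 0.05), and Rpl4 read 1530 ± 234 from Spret and 2450 ± 189 from B6 (-0.69 ± 0.06). The median ratio of the list was 0.08, against -0.13 for autosomal genes, and camera gave an adjusted p = 0.00013 toward Spret. The call was lost with an estimated correlation, at an adjusted p = 0.553 with that setting, while it lay between 9.95e-08 and 0.00843 under the others. The estimated correlation was -0.0091, below the preset 0.01, and that setting tests with the 2 residual degrees of freedom. It has little power, so the loss does not show that correlation among these genes undoes the call. The mean ratio was -0.22, opposite in sign to the median and the test, and without the 4 X-linked members it was 0.18, with a median of 0.10. Fisher's exact test of the called directions gave an adjusted p = 7.17e-07. Camera adjusted p-values of the other 20 lists lay between 0.224 and 0.988. By fry, which asks whether a list moves to either side and does not compare it with other genes, 10 lists passed 0.05, with cortical hem and choroid plexus lowest at an adjusted p = 0.000284. The imprinted list was among them, at a fry adjusted p = 0.0199. It mixes parental origin with strain, so its result is not evidence for a lean. The ribosomal list was not among the 10, at a fry adjusted p = 0.103. Ratios were not centred for fry, so the general lean toward B6 enters that test.

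Metabolic and cell cycle genes also showed calls in both directions. In glycolysis and hypoxia response, 5 of 31 genes were higher from Spret, with Gapdh at 0.24 ± 0.05, and 11 from B6, with Pkm at -0.33 ± 0.04. In cholesterol synthesis, 3 of 24 were higher from Spret, with the synthase gene Hmgcs1 at 0.46 ± 0.05, and 9 from B6, with Srebf2, the transcription factor of the pathway, at -0.32 ± 0.07. In oxidative phosphorylation, 10 of 49 were higher from Spret and 14 from B6. Here the beta and alpha subunits of the ATP synthase differed in direction, with Atp5b at 0.70 ± 0.05 and Atp5a1 at -0.36 ± 0.05. Of 42 cell cycle genes, 3 were higher from Spret, with Cdk4 at 0.25 ± 0.05, and 9 from B6, with the proliferation marker Mki67 at -0.47 ± 0.06. Of 29 microcephaly and centrosome genes, 2 were higher from Spret, with Nin at 0.35 ± 0.10, and 5 from B6, with the lissencephaly gene Pafah1b1 at -0.36 ± 0.06. Of the calls toward B6, 1 in glycolysis and hypoxia response, 2 in cholesterol synthesis and 2 in oxidative phosphorylation were X-linked genes. Adjusted over the list alone, 16, 13, 26, 12 and 7 genes were called in these 5 lists. With centred ratios the counts for Spret and B6 were 6 and 8, 5 and 6, 15 and 10, 4 and 5, and 2 and 5, and Srebf2 lost its call (adjusted p = 0.0674). Cdk4 lost its call without library 1 (0.0513), and Nin without library 2 or library 3 (0.0599 and 0.122). Each gene named here except Atp5b lost its call without limma's trend (0.0593 to 0.205) and without the paired term (0.083 to 0.454), and Gapdh, Srebf2, Cdk4 and Nin with no filter on low values (0.0688 to 0.166).

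In the signalling lists, 6 of 32 Wnt genes were higher from Spret, with Apc, a brake on the pathway, at 0.35 ± 0.06, and 6 from B6, with the receptor Fzd3 at -0.19 ± 0.05. Of 27 Notch genes, 4 were higher from Spret and 1 from B6. Aph1a, a subunit of the protease that releases the Notch intracellular domain, read 110 ± 10.3 from Spret and 43.3 ± 15.0 from B6 (1.38 ± 0.19), and Numbl had -0.36 ± 0.09. Of 29 Hedgehog and cilium genes, 4 were higher from Spret, with Ift140 at 0.29 ± 0.09, and 7 from B6, with the motor Kif3a at -0.29 ± 0.07. Of 40 axon guidance and adhesion genes, 6 were higher from Spret, with the ligand Efnb2 at 0.50 ± 0.06, and 18 from B6, with the receptor Plxna2 at -0.16 ± 0.04. Of 15 interferon and immune genes, 3 were higher from Spret, with B2m, the light chain of class I molecules, at 0.83 ± 0.12, and 4 from B6, with Ifitm2 at -0.64 ± 0.10. Of the calls toward B6, 1 in the Wnt list and 3 in the axon guidance list were X-linked genes. The median and mean ratios differed in sign in the Wnt list (0.06 and -0.10) and in the interferon list (0.23 and -0.08). Adjusted over the list alone, 13, 5, 11, 25 and 8 genes were called in these lists. With centred ratios the counts for Spret and B6 were 7 and 3, 5 and 0, 6 and 3, 9 and 12, and 4 and 4, and Fzd3, Numbl, Kif3a and Plxna2 lost their calls (adjusted p from 0.0682 to 0.732). Without library 1, Fzd3, Ift140 and Plxna2 lost theirs (0.0717 to 0.192), without library 2, Fzd3, Ift140 and Kif3a (0.0523 to 0.136), and without library 3, Fzd3 and Numbl (0.0568 and 0.051). Each gene named here lost its call with no filter on low values (0.0707 to 0.22), each except Aph1a and B2m without limma's trend (0.0642 to 0.342), and each except Aph1a and Ifitm2 without the paired term (0.106 to 0.677).

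**Figure D3:**
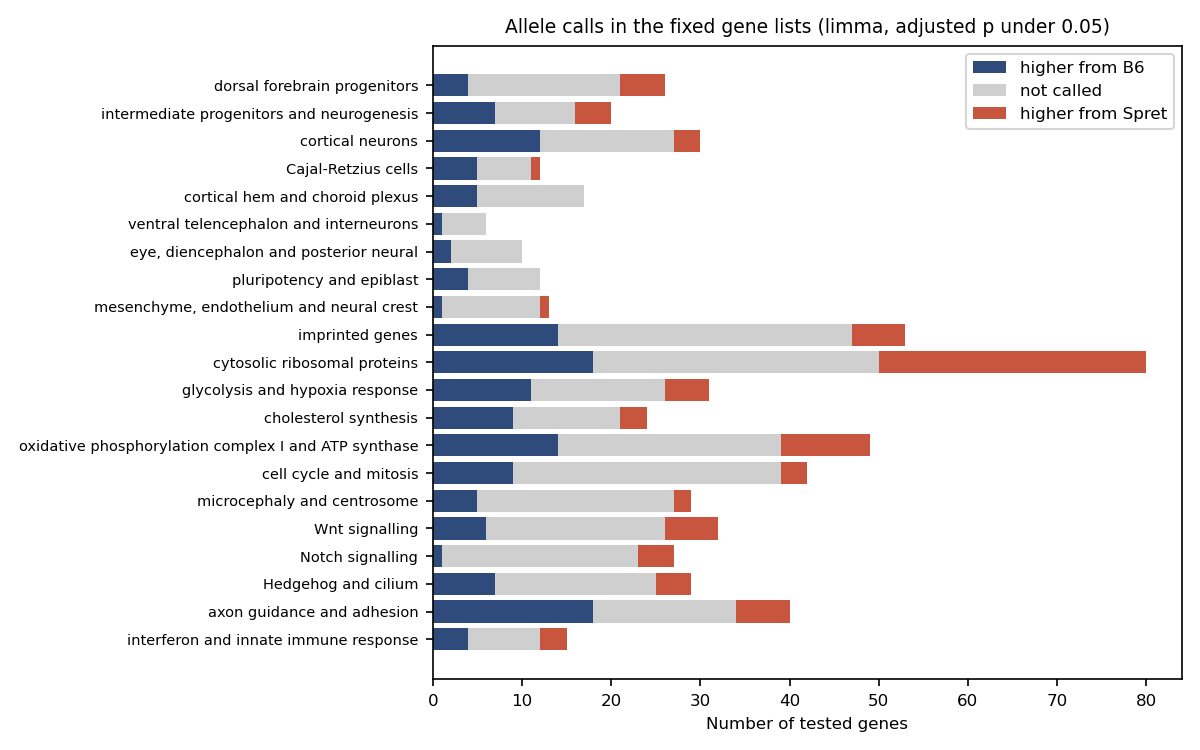
Number of tested genes in each of 21 lists that limma called higher from B6, did not call, or called higher from Spret (horizontal axis, stacked bars). The ribosomal protein bar has 30 genes toward Spret and 18 toward B6, and cortical neurons have 3 and 12. Over all tested genes the counts were 1209 and 3643.

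Genes of the imprinted list, most of which are read mainly from the maternal or the paternal copy in at least some tissues, fell into several kinds. Not every member need be read from 1 copy in these organoids. A call or its absence therefore does not by itself show a departure from imprinting. Of 53 tested, 6 were higher from Spret, 14 from B6 and 33 were not called, with 21 called when adjusted over the list alone. Of the 14 called toward B6, 1 is X-linked. The called genes of highest summed value were Ube3a (-0.35 ± 0.06), Kcnq1ot1 (1.05 ± 0.21), Plagl1 (-0.50 ± 0.07), Inpp5f (-1.80 ± 0.18), Ppp1r9a (-0.30 ± 0.07), Mest (0.41 ± 0.08), Igf2r (-0.32 ± 0.09), Cd81 (-0.28 ± 0.08), Peg10 (-0.54 ± 0.08) and Impact (-0.61 ± 0.09). With centred ratios the counts for Spret and B6 were 14 and 9, so the balance of directions was reversed. Ppp1r9a, Igf2r and Cd81 then lost their calls (limma adjusted p = 0.123, 0.139 and 0.209). Cd81 lost its call without library 1 (0.108), Igf2r without library 2 (0.0804), and Ppp1r9a, Igf2r and Cd81 without library 3 (0.0798, 0.108 and 0.0628). Of these 10 genes, each except Inpp5f and Peg10 lost its call without limma's trend (0.0524 to 0.171), each except Peg10 with no filter on low values (0.0536 to 0.289), and each except Inpp5f without the paired term (0.165 to 0.672). Without library 3 the ratio of Kcnq1ot1 was 0.53, still called. Among 16 genes that are usually read from the paternal copy and had a summed value of at least 100, 13 took between 35% and 65% of their values from Spret in every library. The others were Kcnq1ot1, Nnat and Rtl1. Without strand, values of Rtl1 may belong to its antisense transcript, so its place among the 16 is uncertain. The median Spret share of the 16 was 48.3%, 48.4% and 50.5% in libraries 1, 2 and 3. Snrpn, picked after its values were seen, stood at 54.5%, 57.6% and 47.2%.

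The noncoding RNA genes of the Meg3 domain on chromosome 12, usually read from the maternal copy, were read mainly from B6 in libraries 1 and 2 and mainly from Spret in library 3. These genes fell outside the rule and were chosen after their values were seen. Meg3 took 11.7% of its values from Spret in library 1 (Wilson 95% interval 10.7 to 12.7), 14.5% in library 2 (13.2 to 15.8) and 86.1% in library 3 (85.4 to 86.7). Rian stood at 9.0%, 11.3% and 85.8% and Mirg at 14.7%, 12.2% and 86.9%. The annotated Rtl1, which without strand cannot be told from its antisense transcript, stood at 12.9%, 9.28% and 82.7%. None of these 4 genes was called by limma, since the libraries went in opposite directions. Library 3 also stood apart at Kcnq1ot1, the noncoding RNA of the Kcnq1 domain on chromosome 7, with 81.1% from Spret (79.9 to 82.2) and a summed value of 2981, against 59.7% (54.6 to 64.6) and 424 in library 1 and 58.5% (54.0 to 62.9) and 600 in library 2. Inpp5f stood at 18.8%, 16.4% and 34.0% in libraries 1, 2 and 3, and Peg3 at 48.4%, 49.0% and 60.2%. Nnat went the other way, toward B6, with 43.6%, 42.9% and 19.9%. In these 3 genes and in Snrpn, where library 3 was lower, its Wilson interval did not overlap those of libraries 1 and 2.

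**Figure D4:**
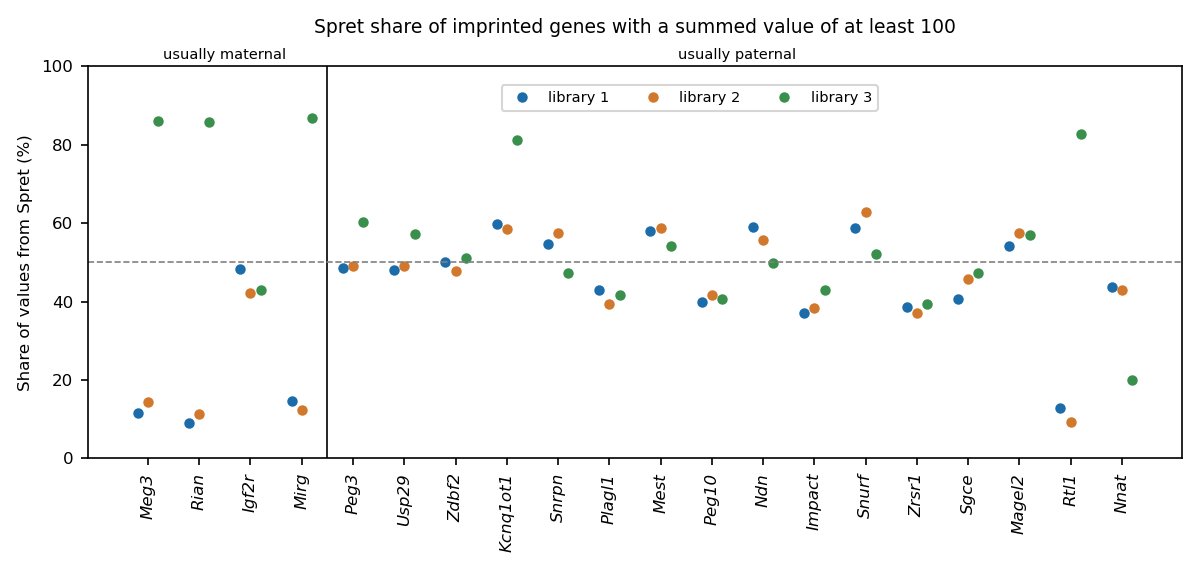
Share of values from Spret (%, vertical axis) for imprinted genes with a summed value of at least 100, with a point per library, grouped by the parental copy that is usually read, and a dashed line at equal shares. Meg3, Rian, Mirg and Rtl1 lie below 15% in libraries 1 and 2 and above 80% in library 3.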

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

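All alternatives here were chosen before the data were examined. The count of 4852 genes was 1236 with no filter on low values, 1537 without the replicate block (267 of them, 17.4%, higher from Spret), 2229 without limma's trend, and between 2667 (without library 1) and 4001 with a library left out. Every gene called both there and in the main result kept its direction. That outcome was fixed in advance without the block, without the trend and under the filters, which leave a gene's ratio as it was. With a pseudocount of 0.5, a pseudocount of 5 and centred ratios, which change the ratio, the shared genes numbered 4728, 4836 and 3611. With a library left out, the ratio still rests on libraries of the main result. Under these settings too a called gene was unlikely to change direction, so the kept directions are weak support. Without the replicate block all 1537 calls were among the 4852. The count with a 2-fold difference, 1586, was 854 with no filter, 592 at a mean value of at least 50 and 985 where both alleles had a mean of at least 5, and lay between 1265 and 1564 with a library left out. Without X-linked and imprinted genes, 4480 genes were called and 1105 differed at least 2-fold. The filters change which genes are tested by construction. For the other settings the cause was not tested. The 1 list called by camera became 0 with an estimated correlation, with 1 list, the ribosomal proteins, at an unadjusted p under 0.05 (0.0263), and it was called under all other settings, also without the block, with adjusted p from 9.95e-08 to 0.00843. Values that changed sign were those of Cdh2 (0.13 with centred ratios, -0.037 to 0.0060 with a library left out), Neurod6 (0.014 centred), Tfap2b (0.066 centred), and, with a library left out, Gad1 (-0.020 without library 1, up to 0.26), Pdgfra (0.026 without library 1, down to -0.31), Tcf7l2 (-0.049 without library 2, up to 0.57) and Barhl2 (-0.41 without library 2, up to 0.27, and -0.016 with a pseudocount of 5). All but Neurod6 were not called in the main result, and the cause was not tested. Of 69 called genes that the rule for named genes takes, 67 and 69 stayed called with pseudocounts of 0.5 and 5, 56 with centred ratios, 27 with no filter, 30 without the trend, 28 without the block, and 52, 57 and 56 without libraries 1, 2 and 3. All 57 autosomal medians stayed below 0 under each of the 3 alternatives tried for them. The edgeR test for read counts, planned for a table of raw reads, was not run, and neither was DESeq2. The deposited values were not raw reads, and whole reads could not be recovered exactly in library 3. Low values limited small differences in simulated data. There, 1.5-fold differences were called in 1 of 21 genes with a mean value below 50 and in 14 of 29 others. Those data had a preset spread and few changed genes, so these shares need not hold for the deposited values.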

Other observations

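Tests chosen only after the result was seen are those of swapped alleles, of wrongly assigned reads, of mixed-in B6 cells and of other splits of the columns. The tests of shared sequence, expression level, the surroundings of Meg3 and neighbouring genes were set before their results were seen.

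Whether the lean of autosomes toward B6 differs between kinds of transcript was not tested. The median log2 ratio of Spret to B6 was -0.12 over 12720 protein-coding genes, -0.28 over 327 long intergenic noncoding RNAs, -0.33 over 268 processed transcripts, -0.12 over 754 antisense genes and -0.54 over 52 small nucleolar RNAs. Over 13 small nuclear RNAs it was 0.06, with 0.19, 0.35 and -0.48 in libraries 1, 2 and 3. Clcn4, on chromosome 7 in laboratory strains, is known to lie on chromosome X in Mus spretus. The tested gene before it, Zfp418, took 45.2% ± 2.82 of its values from Spret (SD, n = 3), and Gm45631, which lies within Clcn4, was also listed at 0.

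The Meg3 domain switched allele in library 3 as a block: of 15 tested genes from Meg3 to Mirg (chromosome 12, 109541001 to 109749460), 14 were read mostly from B6 in libraries 1 and 2 and mostly from Spret in library 3, the exception being Gm27300. Swapped allele columns are argued against by chromosome X, which took 0.0883% of its values from Spret in library 3. Loss or copying of a long B6 segment is argued against by the other 47 tested genes within 2 Mb of Meg3, domain members other than Meg3, Rian, Mirg and Rtl1 included, whose Spret share changed by a median of 1.15 points (95% bootstrap interval -0.44 to 1.84). Among 21 of them that lie outside the domain and had a summed value of at least 100, 0 switched, with changes from -12.8 to 7.12 points. The nearest tested genes outside the domain were Begain, which ends at 109068217, and Ppp2r5c, which starts at 110447120. An event limited to the domain or to the stretch between these 2 genes stays open. So does a candidate biological explanation, a clone in which the imprint of the domain is set the other way. No biological explanation was tested.

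Imprinted genes made up 10 of the 50 autosomal genes that set library 3 apart from the others most, and 7 when either library 1 or library 2 was taken as the odd one, with Meg3, Rian, Mirg and Rtl1 in each case.

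Most genes known to be read from the paternal copy were read from both copies, 13 of 16 in every library. With chromosome X read from B6 and chromosome Y from Spret, the B6 share of these genes is what calls for an explanation. Spret reads assigned to B6 across the genome are argued against by the 5 tested Y-linked genes, where at most 0.423% of values in a library came from B6 (Wilson 95% interval 0.099 to 1.3), and wrong assignment at single loci stays open. An admixture of B6 cells large enough to give these genes their B6 share is argued against by autosomal genes, whose median Spret share was at least 47.78% in each library. A loss of imprinting during culture of the lines may remain as an explanation, and it was not tested.

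Ribosomal protein genes leaned to Spret relative to other genes, with an excess median log2 ratio of 0.21 over other coding genes on autosomes (76 genes, 95% bootstrap interval 0.10 to 0.37). Expression level alone is argued against, since the list median of 0.10 lay at percentile 100 of 10000 lists matched on summed value, of which the highest reached 0.05. Reads shared with processed pseudogenes stay open. Other coding genes with as much sequence of 31 bases shared with another gene had an excess of only 0.019 (-0.009 to 0.078), while ribosomal genes with less sharing kept 0.24 (0.09 to 0.51), an interval that reaches just below the level set beforehand for excluding this explanation. A lean of these genes in the Spret genome is a candidate explanation that these tests leave open. It rests on a list whose call is lost with an estimated correlation, a setting that tests with 2 residual degrees of freedom.

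The hypothesis that neighbouring genes lean to the same allele was not borne out. Among 3827 adjacent called autosomal genes that do not overlap, 61.0% of pairs had the same direction, against 60.4% on average in 10000 shuffles within chromosomes (95% range 59.1 to 61.7). For 1470 pairs less than 100 kb apart the share was 62.3% (permutation p = 0.0514).

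Other splits of the 6 allele columns number 10 with the real one, too few for a share under 0.05. For allele-biased genes, 1 of the 10 splits, the real one, gave as many as 4852, and the highest other split gave 0 by limma, with at most 421 genes at an unadjusted p under 0.05. For genes with a 2-fold difference, 1 of the 10 gave as many as 1586 and the highest other gave 0. For lists, 6 of the 10 gave at least the 1 list of the real split, and the highest other gave 2. The splits that, like the real one, part the alleles of all 3 libraries were 3 others, each with 0 called genes by limma and at most 63 at an unadjusted p under 0.05. The remaining 6 keep both alleles of a library together in 2 of the 3 libraries. In every other split the allelic differences that the libraries share enter the residual spread of the test, so few called genes were bound to result. The gene counts of these splits therefore do not measure how many calls arise by chance.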
